A study of Mus musculus with 6 samples.

How the data were processed

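Hearts of 9-month-old mice carrying 1 targeted allele of Grk2 (Adrbk1, the G protein-coupled receptor kinase 2), written GRK2+/-, were compared with hearts of wild-type littermates, with 3 hearts in each group and 1 Affymetrix expression array per heart. Per the labels' protocols, hearts were arrested with potassium chloride, rinsed, and the upper part was excised and kept in an RNA-stabilising solution before total RNA was extracted and biotinylated cRNA was made; samples of adequate RNA quality had been selected. The deposited values are on the log2 scale, and per the submitters' processing notes RMA and limma were used; versions, and whether all arrays were normalised together, are not given in the sources used here. Per the values, the array medians lay between 6.25 and 6.31 and the deposited log2 values between 3.44 and 15.1. Such values are relative probe brightness after background correction and summarising of probes, so levels near the bottom of the scale carry little signal over background, and levels of different probe sets were not set against each other.

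The table held 45101 probe sets. The 64 control probe sets were left out, and 45037 were tested. The platform annotation used here listed 35890 probe sets; 34945 tested probe sets had 1 gene symbol, 932 listed probe sets had several and were not named, and 9160 tested probe sets (20.3%) were not listed and remained unnamed. For 34741 probe sets the symbol was taken from a RefSeq gene table (assembly GRCm38.p6) through the Entrez identifier. For each gene the probe set with the highest mean over the 6 arrays was kept, which gave 18193 genes. No probe set of the annotation named Grk2 itself, so its level was not analysed here and the genotype labels were not checked by the targeted gene.

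Differences are GRK2+/- minus wild type on the log2 scale, from limma (version 3.58.1, R version 4.3.3; lmFit and eBayes, two-sided, without trend or robust prior) with Benjamini-Hochberg adjustment over probe sets or genes and a threshold of 0.05. Errors of differences are limma's standard errors (SE) with n = 3 hearts per group. With 3 hearts against 3, an exact permutation test cannot give a two-sided p below 0.1, so no such test could pass the threshold, and the number of arrays limits the precision. Counts at an unadjusted p under 0.05 were added after the adjusted counts had been seen.

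Gene lists, 41 in all, covered receptor kinases, adrenergic, insulin and nitric oxide signalling, metabolism and mitochondria, contractile, calcium and stress genes of the heart, matrix, immune, stress-defence, growth and clock genes, and markers of other cell types that the excised piece could hold. Of 978 distinct gene symbols in the lists, 883 matched a measured gene. The 40 lists other than the sex-linked genes, which were read by value, were tested with camera (limma, preset inter-gene correlation of 0.01, lists of at least 5 measured genes) with Benjamini-Hochberg adjustment over the lists. Beside it, camera with an estimated correlation and fry were run; fry's directional test asks whether a list's genes moved, on balance, one way, and its mixed test whether they changed in either direction, and neither compares a list with other genes. Within each list, single genes were also adjusted over the list alone.

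The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took Grk2, the 15 largest changes in each direction among genes past the threshold or, if fewer than 10 genes passed, the 10 genes in each direction with the smallest unadjusted p whose 3 GRK2+/- values all lay on one side of the 3 wild-type values and whose mean was at or above the median of the gene table (7.24); in addition, for each list whose members are described, the 3 members with the smallest p and those past the threshold adjusted over the list alone, up to 6; and every measured sex-linked gene. Symbols that are clone names were not named. Genes near Grk2 were the 50 nearest on each side in the gene order of the GRCm38.p6 table, compared with all other measured genes by Fisher's exact test.

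The steps were tested on simulated data made from the means of the 18193 genes and their spread as estimated by limma. That estimate draws each gene's spread toward a common value, so the simulated spread differed less between genes than in the hearts. In 10 simulations, 92.6% of genes changed 1.4-fold and 100% of genes changed 2-fold were recovered, with a share of false calls of 5.88%. At an unadjusted p under 0.05, camera called 10 of 10 lists of 30 genes shifted by 0.2 on the log2 scale and 0 of 10 unshifted lists. Apart from the immediate early response, every list called below had a median smaller in size than that shift, so recovery of such lists was not tested. Those simulated genes varied independently of each other, unlike genes in tissue. The recovered shares do not carry over to the hearts, where Hpcal1 (1.4-fold) and S100a9 (4.76-fold) did not pass (limma adjusted p = 0.0762 for both). A count of 0 genes past the threshold therefore does not show that few genes changed by such amounts. Alternatives covered the prior of the variance, filters on dim genes, the scaling between arrays, array weights, the probe set kept per gene, the replicate number as a block, each heart left out in turn, the set test and the window around Grk2. Removing each array's trend on gene span and mean level, fitted together, was added after the data were seen. It is called the trend on gene span below. Figures were drawn with matplotlib 3.10.9.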

Results

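Gene expression was measured in hearts of 9-month-old GRK2+/- mice, which lack 1 functional copy of the receptor kinase that desensitises beta-adrenergic and other G protein-coupled receptors, and of wild-type littermates. Each group held 3 hearts with 1 array each, and 45037 probe sets were compared, of which the 34945 with 1 gene symbol gave 18193 named genes. Array medians ranged from 6.25 to 6.31 on the log2 scale. Correlations between arrays over probe sets ranged from 0.99625 to 0.99664 within a group and from 0.99358 to 0.99673 between groups. The first principal component held 38% of the variance and placed the GRK2+/- hearts at -5.44, -21.9 and -15.7 and the wild-type hearts at 4.00, 15.5 and 23.5. The number of arrays limited the precision.

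The comparison of GRK2+/- with wild-type hearts asked how the loss of 1 Grk2 allele alters the transcriptome of the adult heart. Among the 20 genes with the smallest p at or above the median level and without overlap between groups (10 in each direction), S100a9 and S100a8, the subunits of the alarmin calprotectin, had the largest differences, at 2.25 ± 0.33 and 1.97 ± 0.29 on the log2 scale (SE, n = 3 per group), or 4.76-fold and 3.92-fold. Ppargc1b, a coactivator of mitochondrial genes, was higher by 0.84 ± 0.11, the cyclic AMP phosphodiesterase Pde4b by 0.63 ± 0.08, and S1pr3, a receptor for a signalling sphingolipid, by 0.60 ± 0.09. In the other direction, Fam107a, an actin-associated gene induced by glucocorticoids, differed by -1.65 ± 0.19, Fkbp5, a co-chaperone and target of the glucocorticoid receptor, by -1.39 ± 0.20, and the alcohol dehydrogenase Adh1 by -1.26 ± 0.18. All 3 GRK2+/- values of each gene named in this paragraph lay outside the range of the 3 wild-type values. The remaining genes taken by the rule on the higher side were Wtip (0.65 ± 0.08), the dendritic cell marker Cd83 (0.59 ± 0.08), Zfp827 (0.56 ± 0.09), the MAP kinase phosphatase Dusp10 (0.55 ± 0.08) and the transcription factor Rreb1 (0.48 ± 0.08). On the lower side they were the ubiquitin ligase Rnf144b (-0.77 ± 0.12), the steroid sulfate transporter Slc10a6 (-0.69 ± 0.09), the ecto-nucleotidase Nt5e (-0.67 ± 0.11), Ms4a6b (-0.63 ± 0.10), the cyclin-dependent kinase inhibitor Cdkn1a (-0.52 ± 0.09), Hpcal1 (-0.48 ± 0.07) and Ppp1r3c (-0.42 ± 0.07), which targets protein phosphatase to glycogen. Of the probe sets for Pde4b 5 of 6 pointed the same way, and of those for Rreb1 4 of 5. With the mean of a gene's probe sets Pde4b was 0.32, S1pr3 0.36, Rreb1 0.16, Fam107a -1.04, Fkbp5 -0.81, Rnf144b -0.42, Nt5e -0.35 and Ms4a6b -0.40. With the most variable probe set Ppp1r3c was -0.63.

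None of these differences passed the threshold over all genes. With limma, 0 of 18193 genes and 0 of 45037 probe sets had an adjusted p under 0.05, with smallest adjusted p of 0.0632 and 0.103. At an adjusted p under 0.1 there were 57 genes, 31 higher and 26 lower in GRK2+/- hearts, and 0 probe sets. At an unadjusted p under 0.05 there were 2546 genes (14% against 5% by chance; 1146 higher, 1400 lower) and 5780 probe sets (12.8%; 2448 higher, 3332 lower). Which side held more of these genes followed the scaling: 45% were higher as deposited and 63.5% (1546 higher, 890 lower) after each array was centred on its median, which moved the median of all genes from -0.019 to 0.010. The groups did not overlap for 3471 genes (19.1%, against 10% by chance) and 8069 probe sets (17.9%). The count past the threshold was, in place of 0, 56 genes and 41 probe sets without GRK2+/- heart 1, 3 and 9 without GRK2+/- heart 2, and 4 and 6 without GRK2+/- heart 3, while the unadjusted counts were 1614 and 3772 without wild-type heart 3. It was 42 genes and 22 probe sets with a prior that followed the mean level, 6 genes without the dimmer genes, and 12 with array weights and again 12 with the most variable probe set of each gene.

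**Figure D1:**
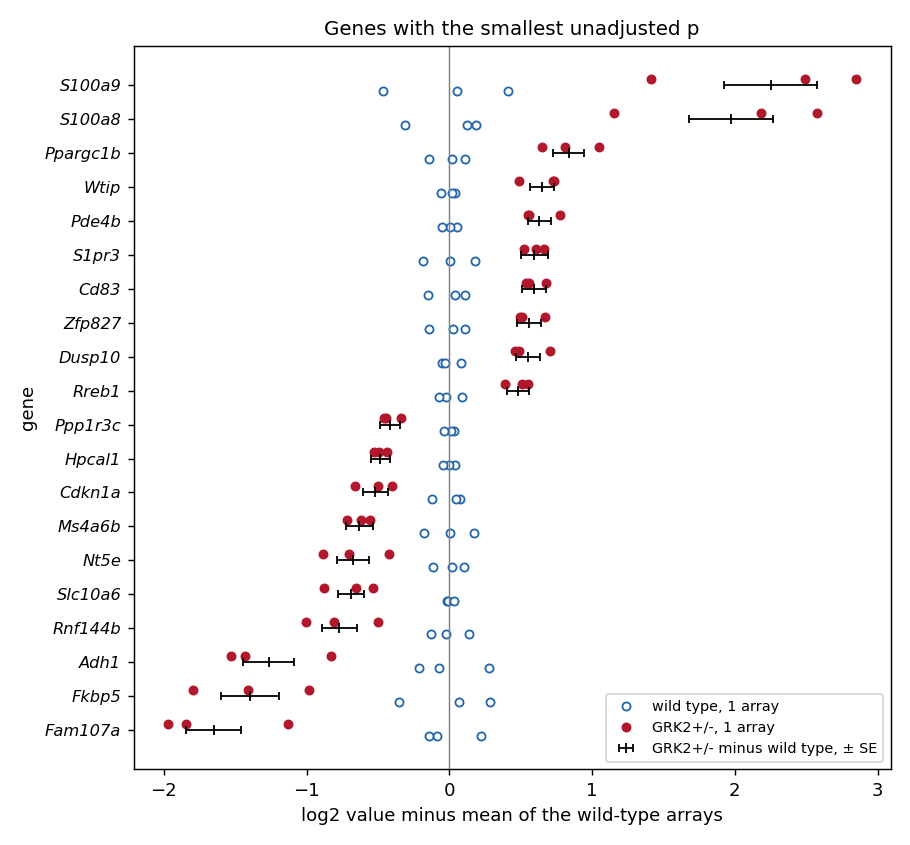
Log2 values of the 10 genes in each direction with the smallest unadjusted p among genes at or above the median level whose groups did not overlap, drawn relative to the wild-type mean of each gene; filled points are the 3 GRK2+/- arrays, open points the 3 wild-type arrays, and black bars the difference ± SE. For S100a9 the GRK2+/- heart nearest to wild type was heart 1, at 8.33 against 6.46 to 7.33 in wild-type hearts.

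Of the 40 gene lists tested, 11 passed the threshold with the preset correlation, 9 higher and 2 lower in GRK2+/- hearts. With an estimated correlation 0 passed (smallest adjusted p = 0.378 with an estimated correlation), and fry's directional test called 0 (smallest adjusted p = 0.0979), whereas its mixed test called 20. Over all genes 0 members of any list passed an adjusted p of 0.05, so every count below of members that passed is adjusted over the list alone. Alongside these lists, the 3′ minus 5′ difference of the beta-actin control probe sets, a measure of RNA integrity and labelling, was 0.98 ± 0.08 in GRK2+/- and 0.78 ± 0.04 in wild-type hearts (SD, n = 3 each), a shift of 0.20. The shift was 0.0245 for Gapdh, 0.0205 for pyruvate carboxylase, -0.095 for the transferrin receptor and -0.27 for 18S rRNA. Of these, only pyruvate carboxylase is a messenger whose 5′ probe set lay neither near the bottom nor near the top of the scale.

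Genes of the immediate early response, which are induced within minutes of a stimulus, were higher as a list in GRK2+/- hearts with the preset correlation. The cause was not tested. The median difference of the 28 genes was 0.45 (camera adjusted p = 6.71e-06; adjusted p = 0.47 with an estimated correlation and 0.442 with fry), with 20 above 0 and 8 below. Adjusted over the list alone, 9 were higher, 0 lower and 19 did not pass. Egr1 was higher by 2.55 ± 0.60 and the orphan nuclear receptor Nr4a1 by 1.46 ± 0.25, followed by Dusp6 (0.55 ± 0.14), Fosb (0.52 ± 0.12), Klf4 (0.52 ± 0.11) and Fosl2 (0.48 ± 0.14; its other probe set pointed the other way, and their mean gave 0.23). The means of Fosb (5.34 in GRK2+/- and 4.82 in wild-type hearts) lay below the median of the gene table (7.24). The GRK2+/- hearts differed among themselves: the mean over the list, relative to wild type, was 0.11, 0.45 and 0.93 in hearts 1, 2 and 3, against -0.051 to 0.070 in wild-type hearts. Without GRK2+/- heart 3 the median was 0.20 (adjusted p = 3.32e-05).

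Genes of adrenergic and cyclic AMP signalling had a median difference of 0.098 over 31 genes (adjusted p = 0.000197; adjusted p = 0.378 with an estimated correlation). In that list 2 genes were higher adjusted over the list alone and 29 did not pass: Pde4b, given above, and Pde4d, another cyclic AMP phosphodiesterase, at 0.30 ± 0.07, with 1 of 2 probe sets in that direction. Akap5, an anchor of protein kinase A, differed by 0.22 ± 0.08 and did not pass. Its means (5.27 in GRK2+/- and 5.06 in wild-type hearts) lay below the median of the gene table (7.24). With the mean of a gene's probe sets Pde4b was 0.32, Pde4d 0.065 and Akap5 0.14. With its most variable probe set Pde4d was -0.17. The list median was 0.055 without GRK2+/- heart 2, 0.050 without wild-type heart 3, 0.052 with the mean of a gene's probe sets (adjusted p = 0.00356) and 0.061 after the trend on gene span was taken out (adjusted p = 0.0238), and the call held in each. The 7 measured receptor kinases and arrestins had a median difference of -0.0043, which was positive (0.025) after centring each array on its median, and none passed (list adjusted p = 0.728).

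Genes of calcium handling and ion channels were higher as a list, with a median difference of 0.085 over 30 genes (adjusted p = 0.0023; adjusted p = 0.378 with an estimated correlation). Adjusted over the list alone, 8 were higher, 1 lower and 21 did not pass. The sodium-calcium exchanger Slc8a1 was higher by 0.50 ± 0.11, the potassium channel subunits Kcnd3 by 0.39 ± 0.10, Kcnd2 by 0.35 ± 0.08 and Kcnj3 by 0.32 ± 0.09, the gap junction protein Gja1 by 0.37 ± 0.11 and the ryanodine receptor Ryr2 by 0.35 ± 0.08. Probe sets of these genes did not all point the same way: 2 of 4 did for Slc8a1 and for Kcnj3, 3 of 4 for Kcnd2 and 1 of 4 for Kcnd3. With the mean of a gene's probe sets these were 0.087 (Slc8a1), 0.15 (Kcnj3), 0.16 (Kcnd2) and 0.049 (Kcnd3). The list median was 0.053 without GRK2+/- heart 3 and 0.054 without wild-type heart 1, and the call held.

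Genes of insulin signalling had a median difference of 0.083 over 31 genes (adjusted p = 0.00358; adjusted p = 0.378 with an estimated correlation), and adjusted over the list alone 8 were higher, 3 lower and 20 did not pass. Igf1 was higher by 0.39 ± 0.08, Gsk3b, the kinase that inhibits glycogen synthase, by 0.35 ± 0.08, Tbc1d4, which controls glucose transporter traffic, by 0.34 ± 0.07, Igf1r by 0.31 ± 0.08 and Rictor by 0.27 ± 0.07, while the transcription factor Foxo3 was lower at -0.32 ± 0.07. Same-direction probe sets numbered 4 of 6 for Gsk3b, 4 of 5 for Rictor and 2 of 5 for Igf1r. The mean of a gene's probe sets gave 0.097, 0.084 and 0.12 for these. Rictor was 0.14 with its most variable probe set. The call ended without the dimmer genes (0.057, adjusted p = 0.107), with the mean of a gene's probe sets (0.021, adjusted p = 0.0682) and after the trend on gene span was taken out (0.014, adjusted p = 0.118).

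Genes of fatty acid uptake and oxidation had a median difference of 0.054 over 35 genes (adjusted p = 0.00852; adjusted p = 0.743 with an estimated correlation), with 1 higher adjusted over the list alone, 0 lower and 34 that did not pass. The gene that passed was Cpt1a, which admits fatty acids to mitochondria (0.38 ± 0.08); the uncoupling protein Ucp3 and the thioesterase Acot1 differed by 0.64 ± 0.18 and 0.70 ± 0.23. Acot1 differed by 0.36 without wild-type heart 2. The call ended without GRK2+/- heart 1 (0.027, adjusted p = 0.206) and without wild-type heart 2 (-0.0019, adjusted p = 0.372), without the dimmer genes (0.054, adjusted p = 0.138), and after the trend on gene span was taken out (0.033, adjusted p = 0.0615). It held after quantile normalisation (0.035, adjusted p = 0.042) and after centring (0.083, adjusted p = 0.00772). Genes of lipid and cholesterol synthesis had a median difference of 0.065 over 34 genes (adjusted p = 0.0182; adjusted p = 0.378 with an estimated correlation). In that list Srebf2, a master regulator of cholesterol synthesis, was higher by 0.34 ± 0.08 and the lipogenic gene Thrsp lower at -0.47 ± 0.09, both adjusted over the list alone, 32 did not pass, and Srebf1 differed by 0.25 ± 0.08. Its adjusted p lay between 0.0534 and 0.0629 without GRK2+/- heart 3 (0.0606), without wild-type heart 1 (0.0534), without genes below the 25th percentile of level (0.0629), after quantile normalisation (0.0547) and after the trend on gene span was taken out (0.0591), and at 0.287 without the dimmer genes. With the most variable probe set of each gene the median was 0.11 (adjusted p = 0.00639). Genes of mitochondrial biogenesis and dynamics had a median difference of 0.026 over 23 genes and did not pass (adjusted p = 0.0536). Ppargc1b was the 1 member that passed adjusted over the list alone, and 22 did not pass. The related coactivator Pprc1 differed by 0.30 ± 0.09 and the mitochondrial kinase Pink1 by 0.14 ± 0.07. The list passed after centring (0.055, adjusted p = 0.0403), with a prior that followed the mean level (adjusted p = 0.0336), with array weights (adjusted p = 0.0386), without GRK2+/- heart 2 (adjusted p = 0.0376) and without wild-type heart 1 (adjusted p = 0.0453). After quantile normalisation it did not (0.012, adjusted p = 0.193). Its median was 0.0023 with the mean of a gene's probe sets, 0.014 after the trend on gene span was taken out, 0.043 without GRK2+/- heart 1, -0.0023 without GRK2+/- heart 3 and -0.013 with the most variable probe set of each gene.

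Genes of angiogenesis and hypoxia were higher as a list in GRK2+/- hearts, with a median difference of 0.11 over 29 genes (adjusted p = 0.000197; adjusted p = 0.378 with an estimated correlation). Adjusted over the list alone, 6 were higher, 0 lower and 23 did not pass. These were the growth factor Vegfc (0.69 ± 0.13), the endothelial receptor Kdr (0.55 ± 0.12), the angiopoietins Angpt1 (0.46 ± 0.13) and Angpt2 (0.39 ± 0.08), Efnb2 (0.40 ± 0.09) and the oxygen-regulated factor Hif1a (0.37 ± 0.12). Same-direction probe sets numbered 3 of 4 for Efnb2, 2 of 4 for Hif1a and 1 of 2 for Angpt2. With the mean of a gene's probe sets these were 0.19, 0.15 and 0.13. Angpt1 was 0.24 with that mean and 0.30 without GRK2+/- heart 3. The levels of Angpt2 (6.97 in GRK2+/- and 6.58 in wild-type hearts) lay below the median of the gene table (7.24). The list median was 0.049 with the mean of a gene's probe sets (adjusted p = 0.00296) and 0.068 after the trend on gene span was taken out (adjusted p = 0.00425), and the call held in both. Markers of smooth muscle and pericytes were higher in the same hearts, with a median of 0.15 over 14 genes (adjusted p = 0.00939; adjusted p = 0.378 with an estimated correlation): smooth muscle myosin Myh11 (0.47 ± 0.09) and Notch3 (0.36 ± 0.10) passed adjusted over the list alone, 12 did not pass, and Abcc9 differed by 0.23 ± 0.08. With the mean of a gene's probe sets Myh11 was 0.27 and Abcc9 0.15. That list's median was 0.075 without GRK2+/- heart 3 and 0.23 with the most variable probe set of each gene. Its adjusted p was 0.0568 with camera on ranks. Markers of epicardium and mesothelium had a median of 0.11 over 13 genes (adjusted p = 0.0195; adjusted p = 0.378 with an estimated correlation). In that list Wt1 (0.51 ± 0.12) passed adjusted over the list alone, 12 did not pass, and Lrrn4 and Efemp1 differed by 0.39 ± 0.13 and 0.33 ± 0.11 (0.25 and 0.22 without GRK2+/- heart 3). The call ended without GRK2+/- heart 1 (0.13, adjusted p = 0.127) and without wild-type heart 1 (0.066, adjusted p = 0.172), without genes below the 25th percentile of level (adjusted p = 0.0649) and with camera on ranks (adjusted p = 0.0513). Without the dimmer genes it could not be tested, since 1 of the 13 was left. Without wild-type heart 3 its median was 0.17.

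Lists that were lower in GRK2+/- hearts were the interferon response and the cell cycle. Interferon-responsive genes had a median difference of -0.155 over 27 genes (adjusted p = 0.00145; adjusted p = 0.729 with an estimated correlation), with 22 below 0, and Ifit3 (-0.59 ± 0.12) was the 1 gene that passed adjusted over the list alone, with 26 that did not. The antiviral genes Xaf1 and Oas2 differed by -0.28 ± 0.09 and -0.24 ± 0.07. Wild-type heart 1 had the highest mean over this list, at 0.24 relative to the wild-type mean, and without it the median was -0.070 (adjusted p = 0.335), whereas it was -0.27 without wild-type heart 3. Cell cycle genes had a median difference of -0.12 over 29 genes (adjusted p = 0.00411; adjusted p = 0.378 with an estimated correlation). In that list Ccna2 (-0.45 ± 0.11) and Birc5 (-0.39 ± 0.09), both genes of dividing cells, passed adjusted over the list alone, 27 did not pass, and Cdk1 differed by -0.56 ± 0.18. The wild-type means of Ccna2 (6.79), Birc5 (5.40) and Cdk1 (6.88) lay below the median gene (7.24). The call ended without wild-type heart 2 (-0.081, adjusted p = 0.0795) and without the dimmer genes (-0.077, adjusted p = 0.157), and the median was -0.071 without GRK2+/- heart 3.

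**Figure D2:**
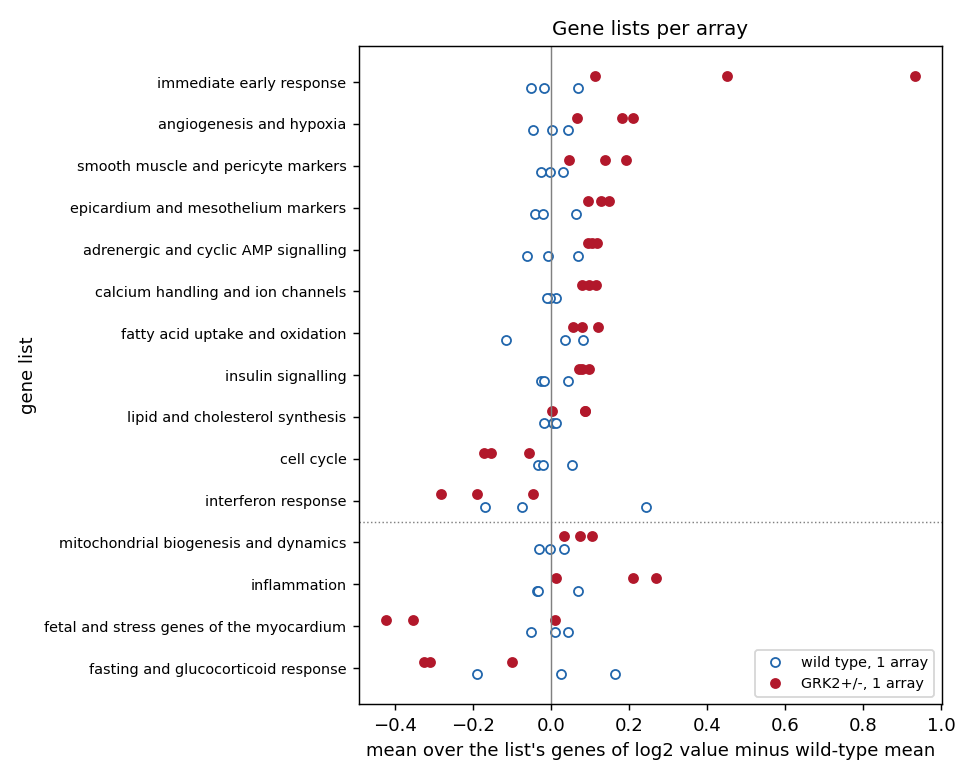
Mean over each list's genes of the log2 value minus the gene's wild-type mean, 1 point per array (filled, GRK2+/-; open, wild type); lists above the dotted line passed the threshold with the preset correlation and the 4 below it did not. The immediate early list spans 0.11 to 0.93 in GRK2+/- hearts, and the interferon list of wild-type heart 1 lies at 0.24.

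Further lists did not pass as a whole and held members that passed adjusted over the list alone. Of 30 inflammation genes 6 were higher, 2 lower and 22 did not pass (median 0.035, adjusted p = 0.0536): beside S100a9 and S100a8 the higher ones included the chemokines Cxcl1 (0.69 ± 0.16; 1.27 with its most variable probe set) and Cxcl12 (0.51 ± 0.09; 2 of 3 probe sets, with a mean of 0.23) and the cytokine Il1b (0.47 ± 0.09), and the chemokine Ccl9 was lower (-0.36 ± 0.10). That list passed without GRK2+/- heart 1 (adjusted p = 0.00837), without wild-type heart 1 (adjusted p = 0.0405), with array weights (adjusted p = 0.0359), with the mean of a gene's probe sets (adjusted p = 0.0303) and after the trend on gene span was taken out (0.057, adjusted p = 0.0385). Its median was 0.0097 without GRK2+/- heart 2 and 0.016 without wild-type heart 3. Of 20 fetal and stress genes of the myocardium 6 were lower, 0 higher and 14 did not pass (median -0.10, adjusted p = 0.057). The lower genes were skeletal alpha-actin Acta1 (-1.33 ± 0.35), the natriuretic peptide Nppa (-1.20 ± 0.28), Ankrd1 (-0.58 ± 0.19), the matricellular gene Ccn2 (-0.35 ± 0.10), Uchl1 (-0.31 ± 0.10) and the protease inhibitor Timp1 (-0.31 ± 0.10). Without GRK2+/- heart 3 Ankrd1 was -0.33 and Timp1 -0.19. GRK2+/- heart 2 had a list mean of 0.0091 against -0.35 and -0.42 in hearts 1 and 3. The list passed without it (adjusted p = 5.11e-05), without wild-type heart 3 (adjusted p = 0.0184) and with the most variable probe set of each gene (-0.20, adjusted p = 0.0225). It also passed after centring (adjusted p = 0.0245), after quantile normalisation (adjusted p = 0.042), with a prior that followed the mean level (adjusted p = 0.0392) and with the replicate number as a block (adjusted p = 0.0113). The same held without genes below the 25th percentile of level (adjusted p = 0.0477), with the mean of a gene's probe sets (adjusted p = 0.0447) and after the trend on gene span was taken out (adjusted p = 0.0394).

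Of 20 genes of the fasting and glucocorticoid response 9 were lower, 4 higher and 7 did not pass (median -0.23, adjusted p = 0.0962). The members with the smallest p were Fkbp5 and Cdkn1a, given above, the transcription factors Zbtb16 (-1.42 ± 0.34) and Cebpd (-0.58 ± 0.12) and the metallothionein Mt1 (-0.47 ± 0.10), all lower, and Cpt1a, which was higher. With the mean of a gene's probe sets Fkbp5 was -0.81 and Mt1 -0.28. Zbtb16, a glucocorticoid target, was 10.5, 9.63 and 8.71 in GRK2+/- hearts 1, 2 and 3 and 10.8 to 11.2 in wild-type hearts. That list passed without GRK2+/- heart 1 (adjusted p = 0.00975), without wild-type heart 2 (adjusted p = 0.0473), after centring (-0.20, adjusted p = 0.0256) and with a prior that followed the mean level (adjusted p = 0.05 after rounding). Its median was -0.15 without wild-type heart 3. Ucp3 (0.64) and Acot1 (0.70), also members, were higher too, so the list's median combined members that moved in opposite directions. Pdk4, the fasting-induced kinase that blocks pyruvate oxidation, is in this list and in the glucose list, where it had the smallest p. It was higher by 0.82 ± 0.23, and by 0.50 without wild-type heart 2.

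**Figure D3:**
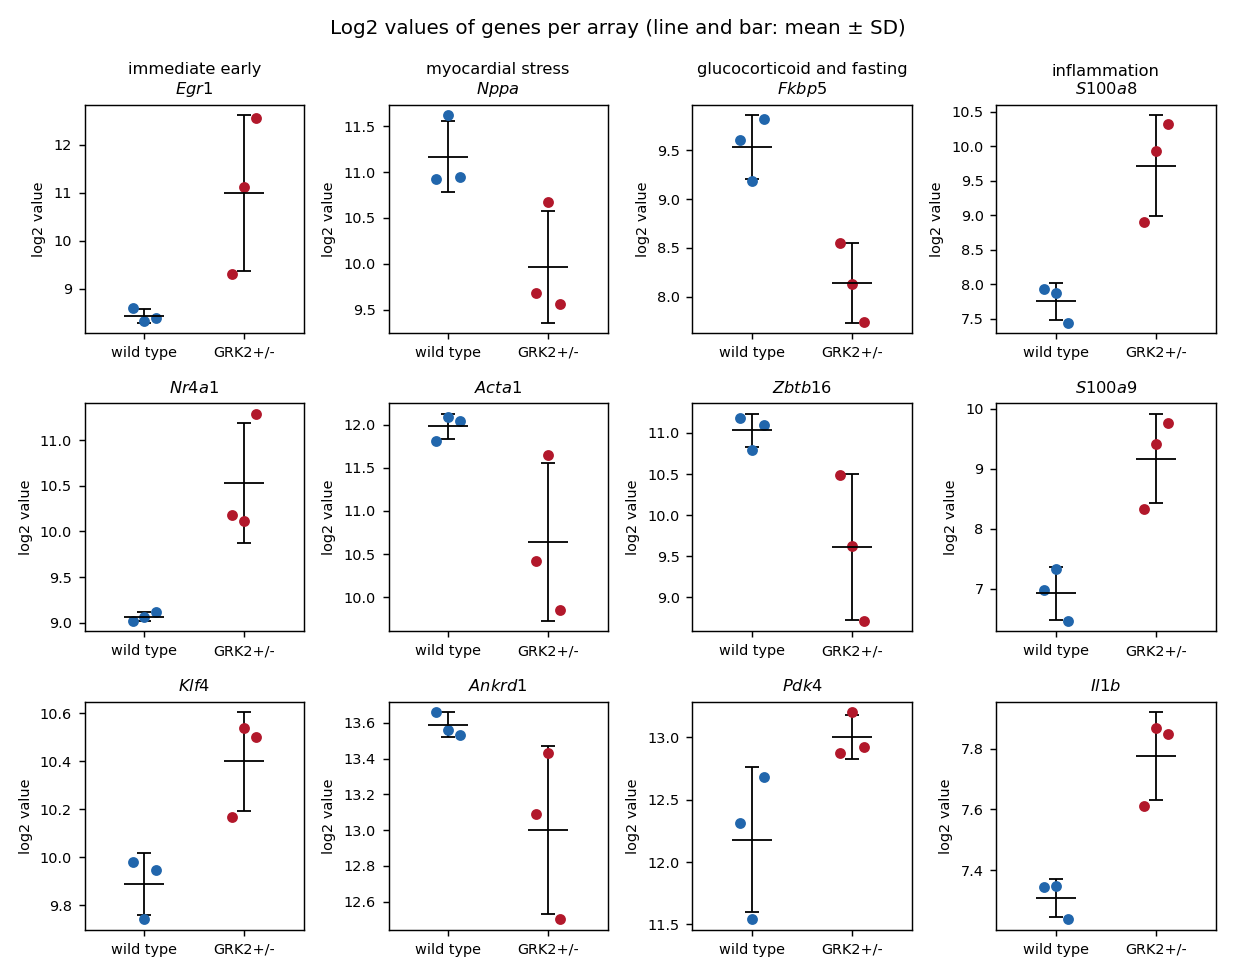
Log2 values of 12 genes per array in wild-type and GRK2+/- hearts, 3 points per group drawn in the order of hearts 1 to 3, with the mean (line) and SD (bar). Egr1 lies at 9.31, 11.1 and 12.6 in GRK2+/- hearts against 8.33 to 8.61 in wild-type hearts, and Nppa at 9.56 to 10.7 against 10.9 to 11.6.

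Metabolic and contractile lists beyond these were near 0. The 69 measured genes of oxidative phosphorylation had a median of 0.012 (adjusted p = 0.286), the 19 of the citrate cycle 0.0069 (0.671), the 30 ribosomal proteins 0.022 (0.271) and the 26 of glucose uptake and glycolysis 0.0012 (0.599; -0.0071 after quantile normalisation), with 0 members past the threshold in each. The 21 sarcomere genes had a median of -0.022 (0.965; 0.0068 after centring on array medians), with 0 members past the threshold, and camera's direction for them was up, against the sign of the median. The 20 clock genes had a median of -0.00084 (0.407; 0.028 after centring), a mean of 0.037 and 0 members past the threshold. For genes of autophagy and atrophy the median was -0.0029 over 23 genes (0.752; 0.026 after centring; camera's direction up), for heat shock and the unfolded protein response -0.0082 over 31 genes (0.684; 0.021 after centring) and for cell death and survival -0.015 over 31 genes (0.477; 0.014 after centring). Values in brackets in this paragraph are camera's adjusted p and, after a semicolon, medians under the scaling named.

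Single members of those and of the remaining lists passed adjusted over the list alone. In the cell death list 4 were lower, 1 higher and 26 did not pass: Cdkn1a and Foxo3, given above, the caspase Casp12 (-0.44 ± 0.08) and the survival gene Bcl2l1 (-0.30 ± 0.09; -0.48 with its most variable probe set) were lower, and the pro-death gene Bcl2l11 was higher (0.57 ± 0.15; 0.31 with the mean of its probe sets). In the extracellular matrix list (41 genes, median 0.020, mean -0.0039, adjusted p = 0.407) the metalloproteinase Mmp14 was higher (0.45 ± 0.09; 2 of 3 probe sets, with a mean of 0.18), the inhibitor Timp4 (-1.08 ± 0.25) and the thrombospondin Thbs4 (-0.38 ± 0.08) lower, and 38 did not pass; that list passed without GRK2+/- heart 3 (0.115, adjusted p = 0.0451). Among 15 thyroid hormone responsive genes (median 0.013, adjusted p = 0.363) Ucp3, Kcnd2 and the receptor gene Thra (0.26 ± 0.07) were higher, Thrsp and the channel gene Kcna5 (-0.34 ± 0.10) lower, and 10 did not pass. In the heat shock list Herpud1, a gene of endoplasmic reticulum stress, was lower (-0.58 ± 0.12) and 30 did not pass, with Hspb1 at -0.19 ± 0.06 and Dnajb4 at -0.26 ± 0.09 (-0.38 with its most variable probe set). In the autophagy list Foxo3 alone passed and 22 did not, with Foxo1 at 0.31 ± 0.10 (2 of 4 probe sets, with a mean of 0.063) and Map1lc3a at 0.14 ± 0.07 (0.073 with the mean of its probe sets and 0.0055 with the most variable). In the oxidative stress list (31 genes, median -0.059, adjusted p = 0.399) Mt1 alone passed and 30 did not, with Gsta3 at -0.59 ± 0.17 (-0.37 without wild-type heart 3). In the nitric oxide and endothelin list (25 genes, median -0.041, adjusted p = 0.822) the guanylate cyclase subunit Gucy1a1 was higher (0.52 ± 0.10; 2 of 3 probe sets, with a mean of 0.17) and 24 did not pass, with Ece1 at 0.21 ± 0.07 (0.076 with the mean of its probe sets, 0.13 after the trend on gene span was taken out) and Agtr1a at 0.16 ± 0.07 (0.099 without wild-type heart 2).

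Genes near Grk2 on its chromosome were compared with the rest because the targeted allele was made in another mouse strain background and can carry flanking sequence. Of 61 measured neighbours, 13 (21.3%) had an unadjusted p under 0.05, against 14.0% of other genes, an odds ratio of 1.67 (95% interval 0.828 to 3.13; Fisher's exact test, two-sided p = 0.135). The odds ratio was 0.981 without wild-type heart 1.

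The sex-linked genes did not separate the groups. Xist, expressed from the inactive X chromosome of females, lay between 6.35 and 6.58 on the 6 arrays, and the Y-linked genes Eif2s3y, Kdm5d and Uty lay between 8.67 and 9.11, 6.48 and 6.66, and 6.84 and 7.11. Group differences were -0.030 ± 0.083 for Xist, -0.030 ± 0.11 for Eif2s3y, -0.012 ± 0.074 for Kdm5d and -0.017 ± 0.081 for Uty, and the signs of Kdm5d and Uty flipped under quantile normalisation and under centring on array medians.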

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

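Of the tests in this part, those on other splits for single genes, on gene span and on RNA degradation were chosen after the results they bear on had been seen; those on other splits for probe sets and lists, on strain sequence, atrial tissue, sex and time of day were set beforehand. The 3′ minus 5′ difference of the beta-actin control probe sets, which the comparisons did not use, was higher by 0.202 on the log2 scale in GRK2+/- hearts, with every GRK2+/- array above every wild-type array (exact two-sided p of 0.1, the smallest possible with 3 against 3). Of the other messenger controls, only pyruvate carboxylase had a 5′ probe set within the usable range, and it did not follow (0.0205). The 5′ probe set of beta-actin itself, at 12.9, lay just under the upper bound of that range. The 5′ probe set of Gapdh (0.0245) lay near the top of the scale, at 14.4. That of the transferrin receptor (-0.0951) lay near the bottom, at 4.36. The control for 18S rRNA (-0.274) is not a messenger, so these 3 could not contradict beta-actin.

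The first pattern was the 11 gene lists past the threshold. A trend on gene span and mean level may account for part of it. Differences and gene span had a Spearman correlation of 0.165 across genes, which are not independent replicates. After each array's trend on span and level was taken out, 8 of the 11 lists were still called. Insulin signalling, fatty acid oxidation and lipid synthesis were lost, their medians moving from 0.083 to 0.014, 0.054 to 0.033 and 0.065 to 0.054. Span and level were fitted together, so these losses cannot be credited to span alone. Unequal RNA degradation stays open: the median shift of 3′ minus 5′ over 4 messenger controls was 0.0225, but only 2 of them had a 5′ probe set within the usable range, beta-actin (0.202) and pyruvate carboxylase (0.0205). With 10 splits of the 6 arrays no share under 0.05 can be reached; the real split gave 11 lists and the highest other 12 (GRK2+/- hearts 1 and 3 with wild-type heart 1), so 2 of the 10 gave as many. An effect of the genotype stays open beside these.

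The second pattern was the excess of genes at an unadjusted p under 0.05. With 10 splits no share under 0.05 can be reached: the real split gave 2546 genes and the highest other 1924, so 1 of 10 was as large, and past the adjusted threshold the real split and the highest other gave 0 genes and 0 probe sets, which all 10 shared. Unequal sex was argued against, since the groups differed by 0 in arrays with high Xist and all 6 arrays carried Y-linked signal. The 61 measured neighbours of Grk2 were too few to hold the excess. Outside them, 14.0% of genes still had such a p, against 5% by chance. This does not cover donor-strain sequence beyond these neighbours or its effects on distant genes, so such sequence stays open as a cause. For the neighbours themselves (odds ratio 1.668, with an interval on both sides of 1) donor-strain sequence cannot be told apart from genotype. Nor can time of day at collection be told apart with these values (median of Dbp-phase minus Arntl-phase clock genes -0.115, between the bounds of 0.1 and 0.3 set for the test). Atrial tissue also stays open: its 5 markers had a median difference of 0.0543, inside the bound of 0.1 set beforehand. That bound was too loose because only 1 of them, Nppa (-1.20), lay above the median gene level. Myl4 (7.24 in GRK2+/- and 7.10 in wild-type hearts) lay close to that level and differed by 0.139. Myl7 (5.61 and 5.50), Sln (5.71 and 5.65) and Bmp10 (6.04 and 6.23) lay lower, where a fall could hardly show. A rise could have shown, and they differed by 0.114, 0.0543 and -0.189. Whether their probe sets respond to atrial tissue was not tested.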

How the results depend on the processing

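Removing the trend on gene span and the counts at an unadjusted p were added after the data had been seen; all other alternatives were set beforehand. The count of genes past the threshold, 0 as analysed, was 42 with a prior that followed the mean level (38 of them among the 57 at an adjusted p under 0.1), 12 with array weights, 12 with the most variable probe set, 6 without the dimmer genes, where fewer genes were tested, 57 at an adjusted p under 0.1, and 0 to 56 with 1 heart left out (56, 3 and 4 without GRK2+/- hearts 1, 2 and 3). For probe sets it was 22 with that prior and 0 to 41 with 1 heart left out (41, 9 and 6 without GRK2+/- hearts 1, 2 and 3). Counts at an unadjusted p were 1553 genes and 3547 probe sets without the dimmer ones, and 1614 to 3031 genes and 3772 to 6862 probe sets with 1 heart left out, lowest without wild-type heart 3. Without the dimmer genes 10 of the 11 called lists could be tested and 6 were called; of the 11, 0 were called with an estimated correlation and 0 with fry. Over the 11 other settings and the 6 fits with 1 heart left out, the lists of immediate early, angiogenesis, adrenergic and calcium genes were called in each. Among lists not called, stress genes of the myocardium were called in 8 of those settings, inflammation and mitochondrial biogenesis in 3 each and the fasting list in 2, and each of these in 2 of the 6 fits with 1 heart left out. The odds ratio near Grk2 was 0.981 to 1.597 with 1 heart left out, below 1 without wild-type heart 1, and did not pass in any setting. With the most variable probe set Pde4d was -0.17 and Bcl6 -0.18. Of the 116 genes named, 110 kept their direction in each setting, and the other 4 beside these were sex-linked. Genes whose groups did not overlap cannot change sign when 1 heart is left out, so the choice of genes fixed part of this count. With 1 heart left out, Xist was -0.092 to 0.026, Eif2s3y -0.17 to 0.054, Kdm5d -0.068 to 0.023 and Uty -0.071 to 0.060. After the span trend was taken out Xist was 0.0027 and Kdm5d 0.0026, after quantile normalisation Kdm5d was 0.015 and Uty 0.0016, after centring 0.017 and 0.012, and with the mean of its probe sets Uty was 0.035. The cause of these shifts was not tested. Replicate numbers are not stated to pair the samples. Same-numbered deviations correlated at -0.145, -0.0197 and 0.00949, which gave no sign of pairing but cannot exclude it with 3 hearts per group. The fit with the replicate number as a block called 1 gene, Nppa, and 12 lists. A sex covariate was not run because the arrays were alike, and camera under a robust prior was not run. Signal over background limits genes below the median level, and the smallest differences most.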

Other observations

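The tests on neutrophil genes and on a second glucocorticoid list were written after the differences of S100a8, S100a9 and Fkbp5 had been seen, and before the values of the tested genes were looked at; the members of both lists named here were picked after that. Markers of other cell types in the excised piece gave a mixed picture. Among 16 endothelial markers (median 0.080, adjusted p = 0.348) the receptor Kdr, given in the report, and the tight junction gene Cldn5 (0.55 ± 0.16; 0.36 without GRK2+/- heart 2) were higher adjusted over the list alone, Robo4 (-0.31 ± 0.08) and Plvap (-0.21 ± 0.07) lower, and 12 did not pass. Among 16 fibroblast markers (median 0.089, adjusted p = 0.239) Mfap5 was lower (-0.53 ± 0.12) and 15 did not pass, with Col1a1 at 0.30 ± 0.11 (0.19 without wild-type heart 3) and Ddr2 at 0.15 ± 0.06 (0.23 with its most variable probe set, 0.077 after the trend on gene span was taken out). Among 17 atrial markers (median 0.0012, mean -0.050, adjusted p = 0.599) the channel gene Kcnj3 was higher, Nppa and Kcna5 lower, and 14 did not pass.

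No member passed in the other marker lists. The median was 0.025 over 18 macrophage and leukocyte markers (adjusted p = 0.671), -0.12 over 12 lymphocyte markers (0.261), -0.062 over 15 nerve and glia markers (0.407), 0.12 over 6 erythroid markers (0.407), -0.11 over 13 markers of thymus, lung and airway (0.113) and 0.0083 over 15 skeletal muscle markers (0.671; mean -0.10). It was -0.0058 over 13 markers of valve, cartilage and bone (0.671; mean 0.020, median 0.023 after centring on array medians) and -0.0062 over 13 adipocyte markers (0.965; 0.023 after centring, with camera's direction up). Values in brackets are camera's adjusted p, with means and medians as named.

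One hypothesis was that S100a8 and S100a9 were higher because the GRK2+/- pieces held more neutrophils or other myeloid cells. Over 20 other neutrophil genes the median difference was -0.039 (9 higher, 11 lower; percentile 51.3 among 10000 random lists matched on level), with Csf3r at 0.33 ± 0.10 (0.22 without wild-type heart 2) and Mpo at -0.39 ± 0.10. A median under 0.1 had been set as evidence against the hypothesis, but 1 of the 20, Lrg1 (10.5 against 10.9 in wild type), lay above the median gene level, so such cells may still contribute and the test left this open.

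Another hypothesis was that glucocorticoid receptor activity was lower in GRK2+/- mice at collection. A second list of 16 glucocorticoid-induced genes had a median difference of -0.161, between the bounds of -0.2 and -0.05 set for the test. Of the 16, 12 were lower (camera p = 0.00332 and p = 0.155 with an estimated correlation). The median lay below all 10000 random lists matched on level. Random lists drew genes independently, so this rank takes no account of genes that vary together or of differences between hearts. At an unadjusted p under 0.05, 6 members lay below 0, among them Arrdc2 (-0.96 ± 0.18), Map3k6 (-0.65 ± 0.16), Sesn1 (-0.57 ± 0.12) and Rasd1 (-0.34 ± 0.08), and 2 lay above it. These were Errfi1 at 0.73 ± 0.24 (0.38 without GRK2+/- heart 3, 0.47 with the mean of its probe sets) and Bcl6 at 0.24 ± 0.07 (0.030 with the mean of its probe sets, -0.18 with the most variable). Such a difference may follow from genotype, stress or the hour of handling, and the values do not tell these apart.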
